A study of Mus musculus with 5 samples.

How the data were processed

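Gene expression was measured by droplet-based single-cell RNA sequencing in 5 mouse libraries, 1 of sorted muscle progenitors and 4 of sorted sarcoma cells, with the 10x Genomics 3′ kit per the labels' protocols. Cells were purified by fluorescence-activated sorting before loading, per the labels' protocols. Reads were aligned and molecules counted by the authors with Cell Ranger 6.0.1, per the file headers, against the mm10 mouse genome, per the submitters' processing notes. The release of the gene annotation and the settings of cell calling are not given in the sources used here. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library, with 28001 features that include 3 added transgenes, and no barcode holds fewer than 500 UMIs. Cells with fewer UMIs cannot be seen here.

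Groups were taken from the labels. The labels do not say that the sarcomas came from separate animals, so p-values measure only the spread between these samples, which may be technical. The pattern of barcodes shared between libraries was checked, and no pair shared more than 22. No files were left out. Sample groups, tests, gene lists, cell type markers and the first set of alternatives were fixed before the data were examined. Clusters were called library-specific, the stand-in for the named-gene rule was chosen, and the comparisons among progenitor-like and library-specific cells were added after the data were seen.

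Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, using Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5. All kept cells were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method (igraph 0.11.9) at resolution 1.0, with no integration of libraries. Clusters were named from fixed markers only. Doublets were not removed in the reported values. Scrublet called 5, 0, 0, 137 and 0 cells in muscle and sarcomas 1 to 4, under 0.5% in 4 of the 5 libraries, so it has not worked there, and the highest 6% of its scores were removed as an alternative.

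For tests, raw counts were summed per library over kept cells, leaving out glial-like and endothelial-like clusters (7907, 7419, 8206, 6896 and 6819 cells in muscle and sarcomas 1 to 4). Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. The fit left 3 residual degrees of freedom. DESeq2 1.42.0, limma-voom 3.58.1, edgeR against a 2-fold change, other scaling, no filter, other cell filters, thinning and leaving out each sarcoma were the alternatives. An adjusted p that DESeq2 left empty stayed empty. Gene lists (36) were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. Levels are CPM (UMI counts of a gene divided by the UMI total of the library or cell class and scaled to 1e6), with exact Poisson intervals. Shares carry exact binomial (Clopper-Pearson) intervals at 95%. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out, which were 384 kept cells in muscle and 120, 264, 144 and 349 in sarcomas 1 to 4. Folds against a library with 0 counts are lower bounds against a floor of 3 counts in that library.

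The rule for named genes took the 12 largest rises and falls among genes past the threshold, 50 CPM or more in the higher group and the same side of muscle in all 4 sarcomas, 2 to 4 members of each list, 8 genes named beforehand, and 3 genes per sarcoma with the largest excess over the other sarcomas. In the main comparison no gene passed, so the 12 genes on each side with the largest gap from muscle to the nearest sarcoma took that place (not all are named), and list members were taken by their mean level. Gene positions come from the mouse annotation of build GRCm38 (mm10), matched by gene identifier for 27645 of the 28001 features (98.7%). The files pair identifiers with symbols, and 121 features have a symbol used more than once.

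The testing steps were checked on simulated counts drawn for the measured genes from their mean levels, their spread between libraries and the library sizes, with 200 genes changed by known amounts. For sums of progenitor-like cells edgeR recovered 75.8% of genes changed by 3 on the log2 scale and 85.1% of those changed by 6, with 26 false calls among 12474 unchanged genes. For library-specific against progenitor-like cells it recovered 39.8% of genes changed by 2 and 90.8% of those changed by 4, with 6 false calls among 14219. For the main comparison the recovery is given with its result. Figures were drawn with matplotlib 3.10.9.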

Results

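Single-cell RNA sequencing was used to profile sorted cells of the Hic1 lineage in 5 libraries from C57BL/6J mice. Hic1 marks mesenchymal progenitors, and in these animals both copies of the gene carry a tamoxifen-activated Cre recombinase that switches on the red reporter tdTomato. The muscle library held tdTomato-positive progenitors of resting hindlimb muscle from an animal with 1 copy of the reporter. The 4 sarcoma libraries held tdTomato-positive cells of epithelioid sarcomas from animals with 2 copies of the reporter and with floxed alleles at both copies of Smarcb1, which Cre can delete. Sarcoma 1 was taken from the shoulder, sarcoma 2 from the head, sarcoma 3 from the head/ear and sarcoma 4 from the hip. Per the labels, animals received 2.5 mg of tamoxifen in 100 µL of oil on 5 days in a row at 8 weeks of age, with a washout of 10 days. Genotype, reporter copies, body site and tumour state differ together between the groups. The labels name the sarcoma cells as endpoint, so age at collection and time since tamoxifen can differ as well. The comparison between the groups is therefore of sarcoma cells with muscle progenitors and not of a Smarcb1 deletion alone.

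The deposited matrices held 39930 cell barcodes, 8658 from muscle and 7834, 8812, 7330 and 7296 from sarcomas 1 to 4. Total UMI counts were 64061069 in muscle and 194120440, 213271163, 151903246 and 199912219 in sarcomas 1 to 4. After filtering, 37519 cells were kept. The median kept cell held 7566 UMIs and 2684 detected genes in muscle, against 24387 ± 3554 UMIs and 4718 ± 161 genes in the sarcomas (mean of library medians ± SD, n = 4). Genes for ribosomal proteins took 11.1% of UMIs in muscle and 16.6% ± 4.42 (SD, n = 4) in the sarcomas. Intervals given for summed counts and shares cover counting error only.

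Smarcb1 (ENSMUSG00000000902), a core subunit of the SWI/SNF chromatin remodelling complex, is a protein-coding gene on the minus strand of chromosome 10 from 75896769 to 75921617 (mm10). Its transcripts were counted at 88.7 CPM in muscle (95% Poisson interval 86.4 to 91.1) and at 2.42, 3.02, 20.3 and 0.474 CPM in sarcomas 1 to 4 (6.56 ± 9.24, SD, n = 4). The log2 fold change of −3.75 ± 1.49 (SE) did not pass the test across all genes (edgeR adjusted p = 0.545). In cells grouped into clusters found almost only in 1 sarcoma library, Smarcb1 lay at 0.357, 0.893, 1.41 and 0.177 CPM. Progenitor-like cells of the same sarcoma libraries held 51.4, 60.9, 57.6 and 76.9 CPM, against 87.1 in progenitor-like cells of muscle. Mural-like cells held 54.9, 78.9, 77.3 and 118 CPM in the sarcomas and 132 in muscle. The labels do not say which part of Smarcb1 the floxed alleles remove, and a 3′ tag outside that part would not check the deletion.

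At 2000 UMIs per cell, 15.8% of muscle cells and 1.37% ± 1.74 (SD, n = 4) of sarcoma cells held a Smarcb1 UMI. The unthinned shares were 46.6% and 8.10%. Among the cells of clusters from 1 library the thinned share was 0.151% ± 0.124 (SD, n = 4), which sets the level that free RNA could give in these libraries at the same depth. Progenitor-like cells of the sarcoma libraries lay above it, at 8.33%, 12.5%, 10.1% and 17.2% in sarcomas 1 to 4, against 15.3% in muscle progenitor-like cells. Thinned to 1000 UMIs, the shares of progenitor-like cells were 3.39% ± 2.70 (SD, n = 4, range 0 to 6.13) in the sarcomas and 8.25% in muscle. The unthinned shares of progenitor-like cells were 60.8% ± 4.84 (SD, n = 4) in the sarcomas and 48.1% in muscle. These values rest on 238, 210, 2215 and 29 progenitor-like cells of sarcomas 1 to 4 and on 6653 of muscle.

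**Figure D1:**
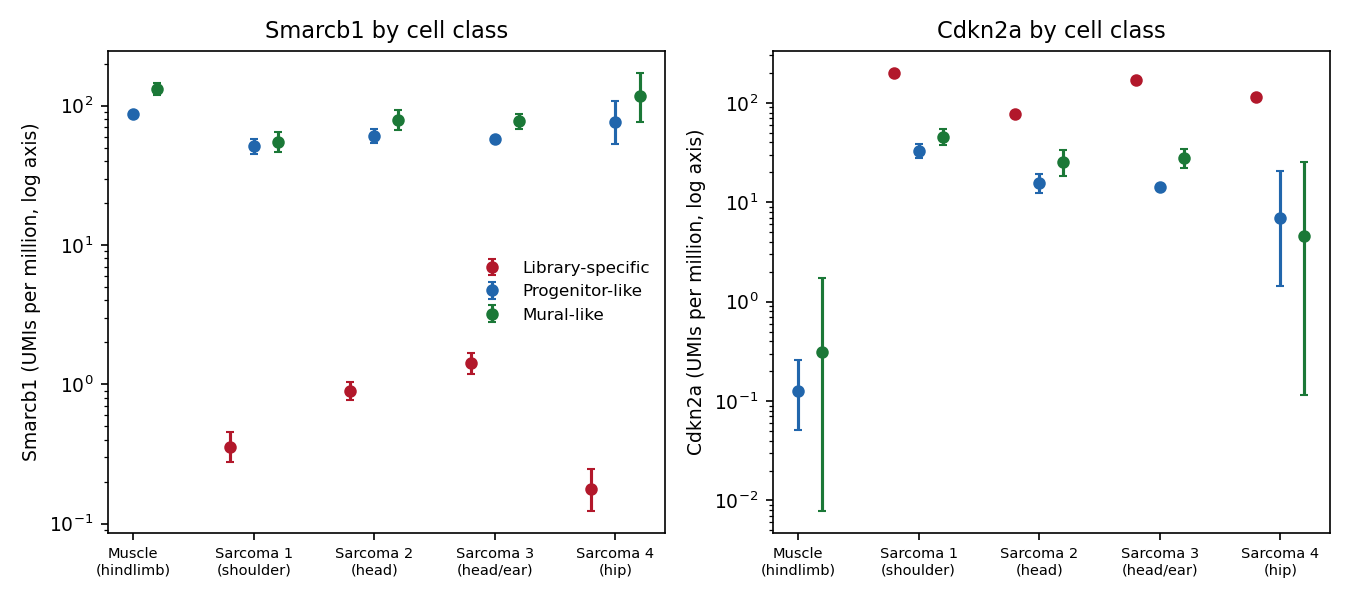
Smarcb1 and Cdkn2a in CPM (log axis) by library and cell class, with 95% Poisson intervals as bars. Library-specific cells hold 0.177 to 1.41 Smarcb1 CPM and progenitor-like cells of the same libraries 51.4 to 76.9, while Cdkn2a is highest in the library-specific cells of every sarcoma.

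Hic1 (ENSMUSG00000043099), a transcriptional repressor on the minus strand of chromosome 11 from 75164565 to 75169519 (mm10), was counted at 49.1 CPM in muscle and at 25.8, 28.2, 25.9 and 0.897 in sarcomas 1 to 4 (log2 fold change −1.11 ± 1.45, SE, edgeR adjusted p = 0.780). The reporter tdTomato was counted at 1137 CPM in muscle and at 713, 358, 1390 and 278 in the sarcomas (log2 fold change −0.62 ± 0.82, SE, edgeR adjusted p = 0.782). Neither difference passed the test, and for tdTomato the muscle level lay between those of the sarcomas.

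The first question was which cell classes the sorted populations held. Muscle was mostly progenitor-like, at 82.1% of kept cells (95% exact binomial interval 81.2 to 82.9), with 9.37% mural-like cells, the contractile cells around vessels, 6.09% tenocyte-like cells and 2.47% glial-like cells. The sarcoma libraries were mostly made of 14 clusters that no fixed marker list named, with 88.3% ± 16.3 of kept cells (SD, n = 4, range 63.99 to 99.2) against 0 of 8107 muscle cells. Progenitor-like cells made up 3.20%, 2.56%, 31.9% and 0.425% of sarcomas 1 to 4, a mean of 9.52%. Mural-like cells made up 1.92% ± 1.30 of sarcoma cells, endothelial-like cells 0.220% ± 0.284, glial-like cells 0.0357% ± 0.0628 and tenocyte-like cells 0.0181% ± 0.0272 (SD, n = 4). Sarcoma 3 held most of the last 3, at 0.633%, 0.130% and 0.0576%, as it did of the progenitor-like cells.

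Each of the 14 unnamed clusters took at least 95% of its cells from 1 sarcoma library, a limit set after the clusters were seen, and these cells are called library-specific here. Most named clusters of muscle cells met the same limit (clusters 0, 1, 2, 3, 5 and 7, with 95.2% to 100% of cells from muscle) and keep their names, so the share of 0 in muscle follows from the naming. Cluster 12, with 1424 cells almost all of sarcoma 2, held few UMIs per cell (a median 0.179 times that of its library) and can be cells of low quality. A cluster of this kind can reflect its library as well as a type of cell. Progenitor-like cells of muscle lay in clusters 0, 1 and 2 and those of the sarcomas mostly in cluster 4, of which 82.7% came from sarcoma 3. Mural-like cells of muscle lay mostly in cluster 5 and those of the sarcomas in cluster 6. No cluster was named haematopoietic-like, myogenic-like, keratinocyte-like or erythroid-like. The sort on tdTomato can set all of these shares. No p-value is given, since the smallest 2-sided exact permutation p of 1 library against 4 is 0.2.

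**Figure D2:**
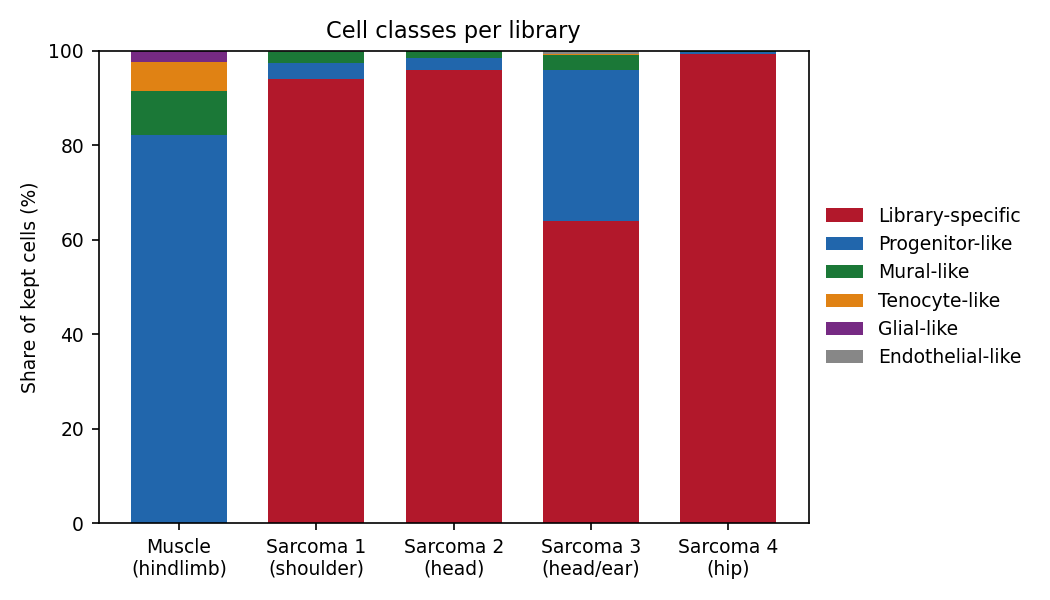
Share of kept cells (%) in each cell class, for the muscle library and the 4 sarcoma libraries, as stacked bars from 0 to 100. Muscle is 82.1% progenitor-like, and library-specific cells take 63.99% to 99.2% of each sarcoma, with the lowest share in sarcoma 3.

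The main comparison asked which genes differ between sarcoma cells and muscle progenitors. Several genes stood far above muscle in all 4 sarcomas. Cdkn2a (ENSMUSG00000044303), which encodes the cell-cycle inhibitor p16 and the p53 activator p19, on the minus strand of chromosome 4 from 89274471 to 89294653 (mm10), was counted at 0.257 CPM in muscle and 125 ± 49.1 in the sarcomas (log2 fold change 9.12 ± 1.03, SE, edgeR adjusted p = 0.428). Spp1, which encodes the secreted matrix protein osteopontin, went from 1.83 to 561 ± 274, the neurofilament gene Nefl from 0.113 to 432 ± 474, and Gchfr, the feedback regulator of GTP cyclohydrolase, from 0.161 to 661 ± 633 CPM (mean ± SD, n = 4). In the other direction, Myoc, which encodes the secreted glycoprotein myocilin, was counted at 1401 in muscle and 2.04 ± 2.14 in the sarcomas, and the lipoprotein lipase gene Lpl at 747 and 15.6 ± 10.9. The surface protease gene Dpp4, a marker of progenitors near the top of the fibroblast hierarchy, was counted at 113 and 0.983 ± 0.682.

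None of these genes passed the test. edgeR called 0 of 18678 genes at an adjusted p of 0.05, with 1709 at an unadjusted p under 0.05. limma-voom also called 0 (1575 unadjusted), while DESeq2 called 1197 of 17098 (692 higher and 505 lower in the sarcomas, 3248 unadjusted). The muscle group has 1 library, which is assumed to vary like the others, and the 4 sarcomas differ widely from each other. In data simulated on this design, edgeR recovered 0% of genes changed by 3 on the log2 scale and 5.56% of those changed by 6, with 0 false calls among 17896 unchanged genes. DESeq2 recovered 45.3% and 83.3% with 339 false calls. With sarcoma 4 set alone against the other 4 libraries, DESeq2 called 1829 genes, more than with muscle set alone, while edgeR called 0 (1989 unadjusted).

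All 4 sarcomas lay above muscle for 4087 of the 18678 genes and below it for 5455. With no difference, muscle would be the lowest or the highest of the 5 libraries for 40% of genes. By at least 3 on the log2 scale, 30 genes lay above muscle in all 4 sarcomas and 108 below. By the same gap sarcoma 4 lay alone below the 4 other libraries for 131 genes and above them for 133, so a single sarcoma exceeds the counts for muscle. The median log2 fold change over all genes was 0.22 with TMM scaling, and scaling by library size moved it by −0.18.

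Because no gene passed the test, genes are named by the gap between muscle and the nearest sarcoma, a rule set after the data were seen. The higher genes also held Pcsk1, a prohormone protease (0.306 in muscle, 73.0 ± 72.2 CPM in the sarcomas), the matrix gene Ltbp2 (1.88, 200 ± 244), the mitotic kinase gene Cdk1 (1.40, 68.0 ± 24.7), the calcium-binding S100a5 (2.11, 405 ± 547), the lipase gene Pla2g7 (4.99, 499 ± 487), the focal adhesion gene Tes (1.88, 142 ± 156) and the nuclear receptor gene Nr4a2 (7.17, 153 ± 45.1). A single sarcoma carried much of some means, as with S100a5 (1210 in sarcoma 2 against 284, 84.6 and 43.3 in sarcomas 1, 3 and 4), Ltbp2 (564 in sarcoma 3) and Tes (370 in sarcoma 4). March11 had 0 counts in muscle and 83.2 ± 84.7 CPM in the sarcomas (range 13.5 to 204), at least 1724-fold higher on average against a floor of 3 counts in the muscle library. The lower genes also held Itih5 (865, 4.44 ± 4.37), the tendon and corneal proteoglycan gene Kera (96.7, 0.259 ± 0.446), Abca8a (581, 7.66 ± 5.79), Stmn4 (56.6, 0.240 ± 0.325), Arhgap20 (76.0, 1.08 ± 0.317), the receptor gene Ret (61.6, 0.607 ± 0.542) and Lims2 (108, 2.06 ± 0.959). The smallest edgeR adjusted p of all genes was 0.243, for Arhgap20 (log2 fold change −5.97 ± 0.35, SE). The heat-shock gene Hspa1a was counted at 4134 in muscle and 89.0 ± 55.4 in the sarcomas, and its reads can be shared with the near-identical Hspa1b.

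**Figure D3:**
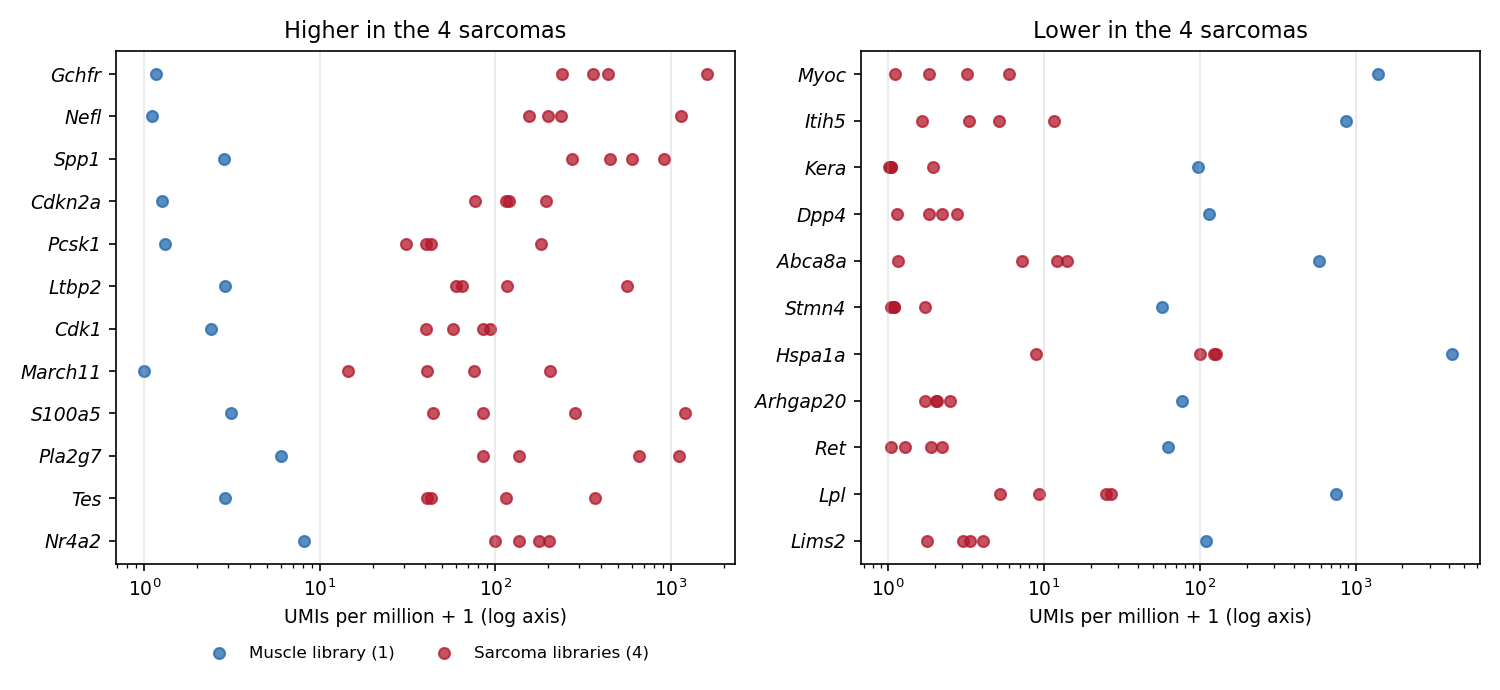
CPM plus 1 (log axis) in the muscle library and in each of the 4 sarcoma libraries, 1 point per library, for genes among the 12 on each side with the largest gap between muscle and the nearest sarcoma. None passed edgeR at an adjusted p of 0.05, and they were chosen for this gap.

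Of 53 measured G2/M genes, 49 lay above muscle in all 4 sarcomas (median log2 fold change 3.74). Among them 41 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.67e-29 with a preset correlation, adjusted p = 0.610 with an estimated correlation). Of 40 S-phase genes, 31 lay above muscle in all 4 and 7 passed when adjusted over the list alone (camera adjusted p = 1.39e-13, adjusted p = 0.671 with an estimated correlation). The ribonucleotide reductase gene Rrm2 was counted at 2.40 in muscle and 84.2 ± 75.4 in the sarcomas, the tubulin gene Tubb4b at 151 and 192 ± 49.4, Cks1b at 85.8 and 182 ± 47.2 and Tipin at 44.8 and 79.1 ± 12.6. The proliferation marker Mki67 was counted at 1.82 and 27.5 ± 16.9 (log2 fold change 4.16 ± 1.27, SE, edgeR adjusted p = 0.498).

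Of 26 measured regulators of the RB and p53 pathways, 17 lay above muscle in all 4 sarcomas and 5 passed when adjusted over the list alone (camera adjusted p = 1.20e-07, adjusted p = 0.407 with an estimated correlation). Besides Cdkn2a, the cyclin gene Ccnd1 was counted at 17.7 in muscle and 545 ± 415 in the sarcomas and the p53 target Cdkn1a at 220 and 362 ± 73.5. Of 28 genes of MYC activity and ribosome assembly, 21 lay above muscle in all 4 and 0 passed when adjusted over the list alone (camera adjusted p = 1.38e-07, adjusted p = 0.671 with an estimated correlation), with Npm1 at 417 and 1245 ± 329 and Ran at 191 and 658 ± 144. Of 19 glycolysis genes, 10 lay above muscle in all 4 sarcomas and 4 below it, with Pkm at 126 and 727 ± 285 and Ldha at 210 and 700 ± 305.

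All 15 measured progenitor markers lay below muscle in the 4 sarcomas, and 3 passed when adjusted over the list alone (camera adjusted p = 1.20e-07, adjusted p = 0.671 with an estimated correlation). These markers also named the clusters, so their lower level adds no evidence beyond the smaller share of progenitor-like cells. Gsn was counted at 32793 in muscle and 2194 ± 2441 in the sarcomas, and Dcn at 16772 and 2016 ± 1695. Of 26 collagen and matrix genes, 17 lay below muscle in all 4 (camera adjusted p = 1.17e-05, adjusted p = 0.671 with an estimated correlation), with Col3a1 at 10061 and 2443 ± 2720. Pdgfra, the receptor that marks these progenitors, was counted at 418 and 194 ± 134 (log2 fold change −0.98, edgeR adjusted p = 0.775).

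Of 18 immediate-early and heat-shock genes, which tissue dissociation is known to induce, 14 lay below muscle in all 4 sarcomas and 4 passed when adjusted over the list alone (camera adjusted p = 7.22e-06, adjusted p = 0.407 with an estimated correlation). Jun was counted at 3361 in muscle and 1041 ± 527 in the sarcomas and Fos at 2679 and 1117 ± 469. Handling of the tissue can therefore differ between the groups together with every other gene group named here.

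Markers of other cells in the sort also differed. The mural list was lower (7 of 10 below in all 4, camera adjusted p = 7.81e-04), with Rgs5 at 385 in muscle and 80.6 ± 63.3 in the sarcomas. The myogenic list was lower too (6 of 7 below, adjusted p = 2.27e-04), with Chodl at 102 and 1.72 ± 3.12 and Acta1 at 24.3 and 2.12 ± 2.14, as was the tenocyte list (3 of 6 below, adjusted p = 0.0368). The adipogenic list (5 of 9 below, adjusted p = 0.0317) and the growth factor list (13 of 36 below, adjusted p = 0.0434) were called lower, the second with a median log2 fold change of −0.43 and a mean of 0.41. The haematopoietic list was higher (5 of 18 above in all 4, adjusted p = 0.00743), at low levels for Cd53 (0 counts in muscle and 5.52 ± 5.44 in the sarcomas, range 0.998 to 12.8, at least 114-fold higher on average). With an estimated correlation these 6 lists had adjusted p = 0.701, 0.568, 0.671, 0.671, 0.610 and 0.744 in the order given. Over all 36 lists, camera called 6 higher and 8 lower with the preset correlation and 0 with the estimated correlation, where the smallest adjusted p was 0.407. fry called 0, with a smallest adjusted p of 0.0652.

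The keratins that mark epithelioid cells were low. Krt8 had 0 counts in muscle and 0.987, 0, 6.98 and 0.428 CPM in sarcomas 1 to 4, at least 43.5-fold higher on average. Krt18 had 0 counts in muscle and 11.2 ± 13.2 CPM in the sarcomas (SD, n = 4, range 0.0189 to 28.3), at least 233-fold higher on average. Of the other SWI/SNF subunits, Arid1a was counted at 65.8 in muscle and 128 ± 13.1 in the sarcomas and Pbrm1 at 143 and 168 ± 3.59, and of 26 members of the list 9 lay above and 11 below muscle in all 4 (camera adjusted p = 0.779). Of 21 polycomb genes, 7 lay above and 5 below (camera adjusted p = 0.966), with the methyltransferase gene Ezh2 at 13.2 and 28.4 ± 6.47 (log2 fold change 1.31 ± 0.51, SE, edgeR adjusted p = 0.545), Rbbp7 at 122 and 191 ± 25.6 and Rbbp4 at 91.2 and 138 (range 124 to 166).

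A further question was how many cells held transcripts of dividing cells. At 2000 UMIs per cell, 0.278% of muscle cells (95% exact binomial interval 0.172 to 0.425) and 11.0%, 10.0%, 2.43% and 3.60% of cells of sarcomas 1 to 4 held a UMI of Mki67 or Top2a, the mitotic topoisomerase (6.77% ± 4.39, SD, n = 4). The unthinned shares were 0.911% and 24.2% ± 11.9. Within the sarcoma libraries the thinned share was 7.12% ± 4.33 in library-specific cells and 1.72% ± 1.58 in progenitor-like cells, against 0.202% in progenitor-like cells of muscle. Mki67 lay below the level of library-specific cells in progenitor-like cells of all 4 sarcomas, so free RNA from the first can account for part of the 1.72%. All 4 sarcomas lay above muscle, and an exact permutation of 1 library against 4 cannot give a p under 0.2. A call on at least 3 UMIs of the S and G2/M lists gave 43.3% in muscle and 67.9% in the sarcomas and reads housekeeping and free RNA as well, so it shows no division by itself.

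The sarcomas came from different body sites, with 1 library for each, and each stood apart by genes of its own. These are described by size without a test. In sarcoma 1, from the shoulder, the neutrophil alarmin gene S100a8 was counted at 152 CPM against at most 1.08 in the other sarcomas, Psca at 69.7 against 0.0101 and the bone matrix gene Dmp1 at 191 against 2.46. In sarcoma 2, from the head, the cranial patterning gene Zic1 was counted at 82.0 against 0.635, the interleukin gene Il12a at 50.8 against 0.961 and Pcp4l1 at 53.6 against 1.17. In sarcoma 3, from the head/ear, the chitinase-like gene Chil1 was counted at 394 against 0.695, the defensin gene Defa24 at 88.9 against 0.104 and the lectin gene Reg3g at 389 against 5.10. In sarcoma 4, from the hip, Mpzl2 was counted at 1061 against 0.260, the posterior homeobox gene Hoxc13 at 446 against 0.140 and the glutathione transferase gene Gsta4 at 1737 against 3.84. Reads of Defa24 can be shared with near-identical members of its family. With cells thinned to 2000 UMIs, 9 of the 12 genes were again among those named, and 8 with library-specific cells alone.

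Genes that record position along the body differed between the sarcomas, some along with site and some against it. Hoxa10, which patterns the hindlimb, was counted at 65.0 CPM in progenitor-like cells of hindlimb muscle and at 69.1 in library-specific cells of the hip sarcoma, against 0.195, 0 and 0 in those of sarcomas 1 to 3. Hoxc10 was counted at 66.5 in hindlimb progenitor-like cells and 201 in the hip sarcoma, against 2.03, 0.0488 and 15.7, and the hindlimb selector Pitx1 at 6.60 and 37.7, against 0.0216, 0.112 and 0.0298. Hoxc6 was counted at 101, 23.9 and 107 in the library-specific cells of sarcomas 1, 3 and 4, and at 1.27 in those of sarcoma 2. Sarcoma 2 came from the head and sarcoma 3 from the head/ear, so Hoxc6 differed between tumours of the head. Other Hox genes went against a match to site. Hoxd10 was counted at 63.4 in library-specific cells of the head sarcoma, 6.17 in those of the hip sarcoma and 1.05 in hindlimb progenitor-like cells. Hoxc8 was counted at 80.01 and Hoxb9 at 26.9 in library-specific cells of the head/ear sarcoma. Hoxb9 and Hoxb8 were counted at 50.5 and 66.1 in those of the hip sarcoma but at 0.0181 and 0.0905 in hindlimb progenitor-like cells. Lhx8, a gene of the cranial mesenchyme, was counted at 165, 260 and 119 in library-specific cells of sarcomas 1 to 3 and at 0.0152 in those of the hip sarcoma, and Barx1 at 102, 0, 32.5 and 0.273. In progenitor-like cells Hoxa10 was counted at 1.61, 0, 0 and 58.2 in sarcomas 1 to 4, the last from 29 cells. The same 29 cells held Hoxb9 at 0 and Hoxb8 at 2.33, below the library-specific cells of the hip sarcoma, and free RNA was not removed from these values. Of the position lists, 28 of 39 Hox genes, 10 of 16 cranial genes and 3 of 4 limb genes reached 10 CPM in a library or class. Site and library cannot be separated with 1 library per site.

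**Figure D4:**
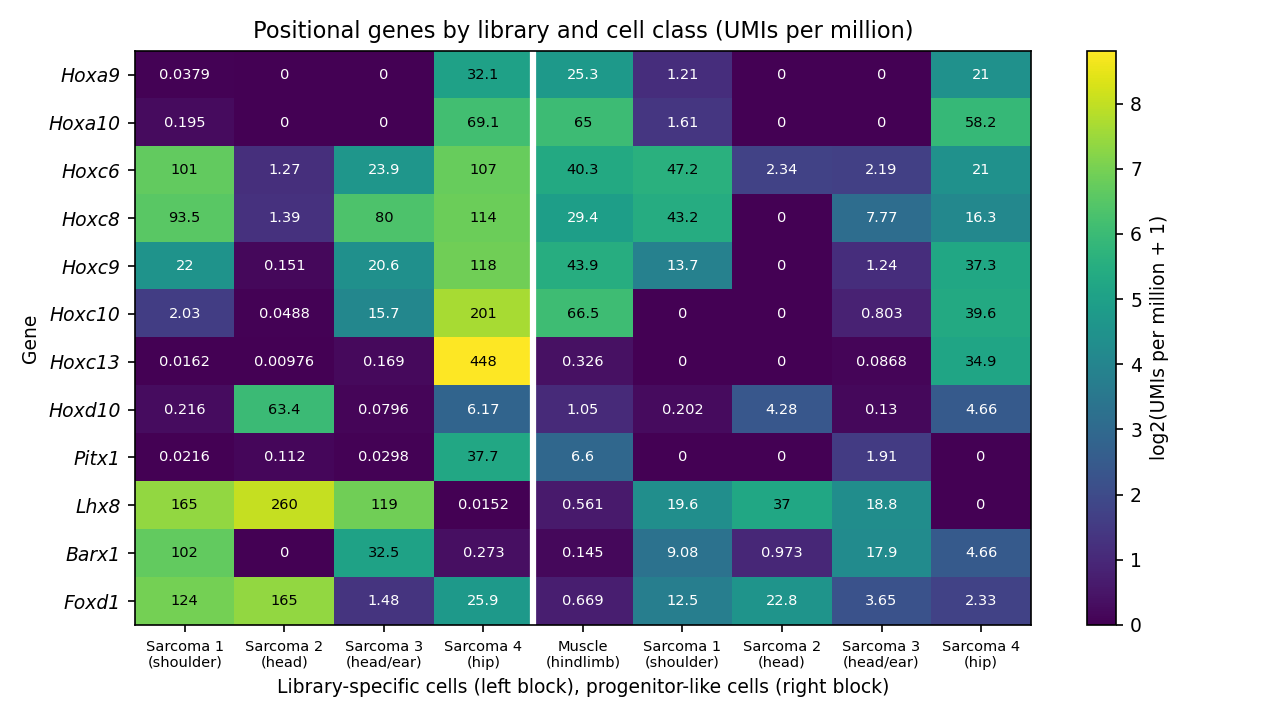
CPM (numbers) of 12 positional genes in library-specific cells of each sarcoma (left block) and progenitor-like cells of each library (right block), coloured by log2 of the value plus 1. Hoxa10 reaches 69.1 in library-specific cells of the hip sarcoma and 65.0 in progenitor-like cells of hindlimb muscle, and at most 1.61 in the other sarcomas.

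Expression was also summarised by chromosome, in library-specific cells of each sarcoma relative to progenitor-like cells of muscle. On chromosome 4 the median log2 ratio of sarcoma 4 was −0.29 over 260 genes, with 69.6% of them below 0. The other 79 medians of a library and chromosome lay between −0.09 and 0.17, and chromosome 4 lay between 0.02 and 0.07 in the other 3 sarcomas. This summary was chosen after the data were seen and has no replicate.

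**Figure D5:**
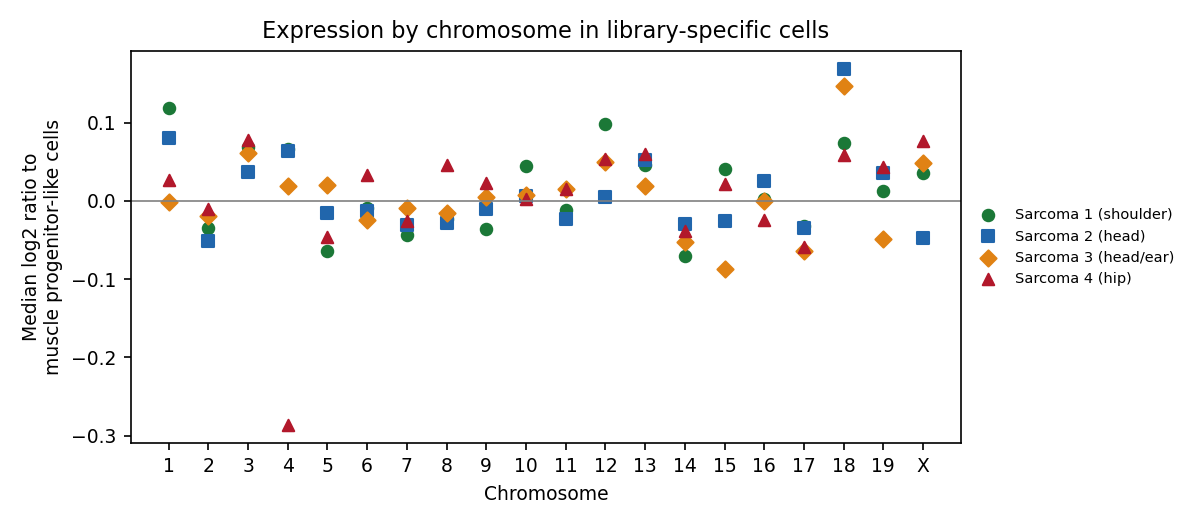
Median log2 ratio of CPM, library-specific cells over muscle progenitor-like cells, by chromosome (horizontal axis) and sarcoma library (colour and shape). Sarcoma 4 lies at −0.29 on chromosome 4, and every other point lies between −0.09 and 0.17.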

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

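The tests of free RNA, of shared barcodes, of the share of cells with Smarcb1 and of library preparations in their present split were chosen after the results were seen, and those of depth and body site were written before theirs. A sarcoma library is listed here when its gap to the nearest of the others was beyond Dixon's limit for 4 samples. Of 72 values tested, 16 were beyond it, 9 of them with sarcoma 3 as the highest or lowest. Chance gives about 1 in 20 only for independent values with a normal spread. These values were mostly raw CPM and shares of cells, and many depend on each other, so the rate is no test here.

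Sarcoma 3 stood apart in its cells. It held 63.99% library-specific, 31.9% progenitor-like and 0.130% glial-like cells, the lowest share of the first and the highest of the others. The library-specific and progenitor-like shares mirror each other and are not separate results. Its level of Smarcb1, the highest at 20.3 CPM, goes with them. Its progenitor-like cells held 57.6 CPM and its library-specific cells 1.41. Among other genes sarcoma 3 was highest for Krt8 (6.98), Ltbp2 (564), Kera (0.928), Stmn4 (0.728) and Chodl (6.39). Sarcoma 2 was highest for Gchfr (1603) and Pcsk1 (181) and sarcoma 1 for Nefl (1141). Sarcoma 4 was highest for Rrm2 (196) and Igfbp6 (7139) and lowest for Hic1 (0.897) and Pbrm1 (163), the last within a narrow range over the 4 sarcomas.

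All 12 genes named for standing out in 1 sarcoma were beyond the limit too, as they were picked for it. They are S100a8 (152), Psca (69.7) and Dmp1 (191) in sarcoma 1, Zic1 (82.0), Il12a (50.8) and Pcp4l1 (53.6) in sarcoma 2, Chil1 (394), Defa24 (88.9) and Reg3g (389) in sarcoma 3, and Mpzl2 (1061), Hoxc13 (446) and Gsta4 (1737) in sarcoma 4, in CPM.

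Progenitor-like cells in the sarcoma libraries kept Smarcb1 transcripts. Free RNA in the droplets argues for a level at or below that of all barcodes pooled, and progenitor-like cells held 20.8, 20.2, 2.83 and 157 times that level in sarcomas 1 to 4, so free RNA alone is excluded as the source. Barcodes carried over from the muscle library are excluded as well, since at most 0.271% of progenitor-like barcodes of a sarcoma library were also muscle barcodes. A candidate explanation is that these are tdTomato-positive cells of the host in which Smarcb1 was not deleted, but their share with a Smarcb1 UMI at 2000 UMIs was as low as 0.545 of that in muscle (sarcoma 1, 95% counting interval 0.333 to 0.832), which leaves open a mixture with cells that lost it. Thinned to 1000 UMIs, the sarcoma mean was 3.39% (range 0 to 6.13) against 8.25% in muscle. The sort and the unknown extent of the deletion keep this explanation open.

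The 14 library-specific clusters separated each sarcoma from the others. A difference between library preparations was taken to reach all cells of a library. At 1825006 UMIs, library-specific cells of sarcomas 1 and 2, 1 and 3, and 2 and 3 differed by 4-fold at 97, 196 and 167 genes outside the variable genes. Progenitor-like cells differed at 4, 19 and 17 and mural-like cells at 4, 16 and 22, so the lowest ratio was 7.59. The classes come from clustering these same cells, and library-specific clusters were chosen for coming from 1 library. The ratio therefore cannot exclude preparation for sarcomas 1 to 3. For the pairs with sarcoma 4, at 220554 UMIs, the lowest ratio was 2.56. It rests on 29 progenitor-like and 19 mural-like cells, so preparation stays open there as well. Depth is excluded, since 99.2% of library-specific cells lay in clusters of 1 library after thinning to 2000 UMIs. Body site may contribute, but the pair of head sarcomas ranked 2 among the 6 correlations across genes (0.803, where sarcomas 1 and 2 reached 0.867), and with 1 library per site it cannot be told apart from differences between tumours. Whether the clusters reflect separate tumours stays open.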

How the results depend on the processing

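The alternatives chosen after seeing the data were removal of the highest 6% of Scrublet scores or of cluster 12 with few UMIs per cell, the 2 sets limited to named clusters, all alternatives of the comparisons of progenitor-like and library-specific cells, library-specific clusters alone for differences between sarcomas, and leaving out each sarcoma for shares and target genes. Part of the named genes were chosen for a large gap from muscle in all 4 sarcomas, so their signs could hardly turn under most alternatives. Of 1096 values for 61 named genes under the alternatives, 1080 kept their sign, a count that was thus partly fixed in advance. The threshold was passed by 32 of these genes with DESeq2, by 15 in progenitor-like cells and by 3 in library-specific against muscle progenitor-like cells, and by 0 under the other alternatives. Of 150 values for the main results, 129 stayed close to the main value, which does not test their direction. Sarcoma means had to stay within 1 SD of the 4, a loose rule where the sarcomas differ widely. Muscle shares had to stay inside their exact binomial interval, and counts of genes or lists near the main count. Of the 129 values, 36 are means without 1 sarcoma, which cannot move by 1 SD of the 4, and of the other 114 values 93 stayed close. The count of 0 genes for sarcoma against muscle became 1197 with DESeq2, whose simulated false calls were many, 448 with progenitor-like clusters only, where the sarcomas vary less, and 4 with library-specific clusters against muscle progenitor-like clusters (Krtdap, Arhgap20, Dpp4 and Itih5, named after their values were seen). It stayed 0 with edgeR under every other alternative and without each sarcoma, where 994 to 2541 genes had an unadjusted p under 0.05. The 14 called lists became 0 with an estimated correlation. For genes changed in progenitor-like cells, 448 became 1078 with DESeq2, 1948 with limma-voom and 336 to 1017 without each sarcoma, the highest without sarcoma 3. For library-specific against progenitor-like cells, 1215 became 3808 with DESeq2, 2441 with limma-voom and 719 with no replicate block. Without each sarcoma it became 92 to 1493 (142, 92 and 252 without sarcomas 1, 2 and 3). Among the genes called against muscle progenitor-like clusters, Dpp4 is also a marker that named those clusters, so its call was partly fixed by the naming.

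Shares of cells moved for glial-like cells of muscle (0.345% at resolution 0.5), library-specific cells of muscle (0.0578% with no cell filter), progenitor-like cells of muscle (84.2% at resolution 0.5) and tenocyte-like cells of the sarcomas (1.20% at resolution 2.0). The last move came from sarcoma 3, where the tenocyte-like share went from 0.0576% to 4.62% and the progenitor-like share from 31.9% to 27.3%. In the other sarcomas at most 0.0942% of cells were tenocyte-like at resolution 2.0. Without sarcoma 3 the sarcoma means were 2.06% for progenitor-like, 0.0827% for endothelial-like, 0.00448% for glial-like and 0.00488% for tenocyte-like cells and 1.97 CPM for Smarcb1, against 9.52%, 0.220%, 0.0357%, 0.0181% and 6.56 CPM with it. The share of cycling cells was 24.2% and 0.911% in sarcomas and muscle when not thinned, and 67.9% and 43.3% with at least 3 UMIs of the S and G2/M lists. With progenitor-like clusters only, log2 fold changes turned for tdTomato (0.11), Col3a1 (0.40), Cdkn1a (−0.95), Chodl (1.37), Ndufa4l2 (1.11), Thbs4 (2.44), Fmod (3.54), Fabp4 (1.26) and Arid1a (−0.0630). With library-specific against muscle progenitor-like clusters they turned for Thbs4 (0.82) and Fmod (2.84). Igfbp6 turned without sarcoma 1 (0.05), 2 (0.0816) or 3 (0.0416), with a range of −4.07 to 0.0816 without each sarcoma. Igfbp7 turned with limma-voom (−0.0404) and without sarcoma 4 (−0.65), with a range of −0.65 to 0.86 without each sarcoma. None of these passed a test, and the cause was not tested. Sarcoma and muscle libraries could not be paired, because the muscle group has 1 library and a replicate number is no pairing. Their small number limits what the 29 progenitor-like and 19 mural-like cells of sarcoma 4 can show.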

Other observations

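All comparisons in this part were chosen after the data were seen, as were the tests of swapped classes, of chromosome windows and of reference cells, while the test of the spread between cells was written before its result. Progenitor-like cells of the sarcoma libraries were set against those of muscle, where the lone muscle library is assumed to vary like the others. The collagenase gene Mmp13 rose from 0.0724 to 271 ± 255 CPM (mean ± SD, n = 4), the neurotrophin gene Bdnf from 0.0543 to 102 ± 83.1 and the acute-phase gene Hp from 0.326 to 228 ± 150. Tnc, which encodes tenascin, rose by 6.37 ± 0.53 on the log2 scale (SE, edgeR adjusted p = 0.00527), the crosslinking enzyme gene Lox by 4.42 ± 0.55 (adjusted p = 0.0157), the collagen gene Col12a1 by 3.71 ± 0.42 (adjusted p = 0.0132), and Timp1, Wisp1, Fbn2 and Lrrc15 rose too. Other matrix genes fell, among them Col4a1 (−2.03), Hmcn2 (−4.78) and Col6a6 (−5.74), and the list of 26 collagen and matrix genes was not called (3 rose and 1 fell, camera adjusted p = 0.317). Of 21 proteases and inhibitors 4 rose (Mmp13, Timp1, Plaur and Adamts4), and this list was called by fry (adjusted p = 0.00927) and by camera (adjusted p = 8.67e-04, adjusted p = 0.309 with an estimated correlation). The markers that name this class were lower in the sarcomas (3 of 15 fell, camera adjusted p = 3.25e-04, adjusted p = 0.309 with an estimated correlation), so the cells compared may not be the same class. At resolution 2.0 sarcoma 3 held 321 tenocyte-like cells, against 4 at resolution 1.0, and fewer progenitor-like cells (1898 against 2215). Markers of other cells moved as well. The tenocyte list was higher (0 of 6 past the threshold, adjusted p = 0.0238, adjusted p = 0.487 with an estimated correlation). The myogenic list was lower (2 of 6 fell, camera adjusted p = 0.00784, adjusted p = 0.373 with an estimated correlation). The haematopoietic list was higher (camera adjusted p = 2.21e-05, adjusted p = 0.309 with an estimated correlation), with Cd53 at 0 counts in muscle and 31.7 ± 28.5 CPM in the sarcomas (adjusted p = 0.0343). The mural list was higher (adjusted p = 0.00872, adjusted p = 0.373 with an estimated correlation), with rises of Acta2 (4.89), Tagln (4.99) and Mcam (3.89), and the immediate-early list was lower (adjusted p = 0.00784, adjusted p = 0.480 with an estimated correlation). Over 33 lists camera called 15 higher and 4 lower, and 0 with an estimated correlation. Falls included the granin family gene Scg3 (−6.94 ± 0.54, adjusted p = 0.00490), Bmp4 (−4.74 ± 0.79, adjusted p = 0.0320), Bmp2 (−4.47 ± 0.75, adjusted p = 0.0325) and Hspa1a (−4.72 ± 0.61, adjusted p = 0.0169), the last shared with Hspa1b. edgeR called 448 of 13102 genes, 200 higher and 248 lower (2422 unadjusted), and 1017 without sarcoma 3. With each sarcoma in turn set alone against the other 4 libraries edgeR called 0 (143 to 690 unadjusted), limma-voom 0 and DESeq2 at most 30, but muscle then widens the spread of the other group. Of the 200 rises, 101 lay above the level of library-specific cells in all 4 sarcomas, which free RNA from those cells cannot give, and 16 lay below it in all 4, Cdkn2a among them (log2 fold change 7.22 ± 1.06, SE, adjusted p = 0.0238). Smarcb1 did not pass (−0.48 ± 0.24, adjusted p = 0.350). Muscle cells of this class lay in clusters 0, 1 and 2 and sarcoma cells in cluster 4. Among the named rises of the protease and mural lists, Mmp13, Timp1 and Tagln lay above library-specific cells in all 4 sarcomas. For Timp1 the margin was narrow in sarcomas 1 to 3 (2048 against 1971 CPM in sarcoma 1). Plaur and Mcam lay below library-specific cells in 3 sarcomas, Adamts4 in 2 and Acta2 in 1. Free RNA from library-specific cells can account for part of such rises.

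Within the sarcoma libraries, library-specific cells were set against progenitor-like cells with the library as a block. Smarcb1 fell by 6.74 on the log2 scale (SE 0.64, edgeR adjusted p = 0.00973, lower in 4 of 4 libraries) and Cdkn2a rose by 3.02 ± 0.32 (adjusted p = 0.0121). The remodelling genes Arid1a (1.18 ± 0.12, adjusted p = 0.0111) and Smarca4 (1.20 ± 0.14, adjusted p = 0.0137), the p53 gene Trp53 (0.88 ± 0.15, adjusted p = 0.0313), its targets Cdkn1a (1.82 ± 0.23, adjusted p = 0.0174) and Mdm2 (1.54 ± 0.29, adjusted p = 0.0376) and the fetal chromatin gene Hmga2 (3.33 ± 0.50, adjusted p = 0.0240, higher in 3 of 4) rose as well. Of 39 S-phase genes outside the variable genes 16 rose, such as Mcm3 (1.77 ± 0.32, adjusted p = 0.0344) and Mcm6 (1.05 ± 0.17, adjusted p = 0.0295). Of 39 G2/M genes outside the variable genes 8 rose. Variable genes, Mki67 and Cdk1 among them, were left out of these counts. Falls included Col3a1 (−3.83 ± 0.42, adjusted p = 0.0126), Col6a3 (−3.95 ± 0.62, adjusted p = 0.0264), Fbn1 (−3.94 ± 0.50, adjusted p = 0.0174), the collagen hydroxylase gene P4ha2 (−5.04 ± 0.55, adjusted p = 0.0126) and tdTomato (−1.03 ± 0.21, adjusted p = 0.0463). edgeR called 1215 of 13569 genes outside the variable genes, 568 higher and 647 lower (3927 unadjusted), but these p-values are too small because the classes come from clustering the same cells, and the count was 142, 92 and 252 without sarcomas 1, 2 and 3. Swapping the classes within libraries gives only 8 splits, too few for a share under 0.05. The real split gave 1215 genes and was the only 1 of the 8 with as many, and the highest of the others was 0. That outcome follows from classes that clustering had set apart, since a swap mixes them, so it adds no support.

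Lower expression of chromosome 4 in library-specific cells of sarcoma 4 was found by looking through all chromosomes. The choice of reference cells is excluded as the cause, since the median log2 ratio was −0.29, −0.28, −0.23 and −0.34 against progenitor-like cells of muscle, progenitor-like and mural-like cells of the same library and library-specific cells of the other sarcomas (highest −0.235). A few genes or 1 segment could still contribute, because 7 of 8 windows of 20 Mb lay between −0.58 and −0.18 but the window from 60 to 80 Mb lay at −0.0126 over only 5 genes. Loss of a copy in part of the cells may be a candidate explanation. Chromosome 4 gave a mean 3.95% of UMIs against 5.85%, 5.77% and 5.64% in sarcomas 1 to 3. The SD of this share between cells, beyond counting error, was 1.24 times the largest of theirs, just short of the bound set beforehand. Divided by the mean share it was 1.77 times the largest, but chromosome 4 then ranked only 12 among the 20 chromosomes of sarcoma 4. In the 3 clusters of library-specific cells of sarcoma 4, the median log2 ratio lay between −0.302 and −0.257. These values point different ways, so the explanation stays open. Chromosome 19 took 14.5% of UMIs in sarcoma 4 against 5.08%, 4.68% and 8.05%, which lowers every other share and adds spread to it. Outside chromosome 19, a step chosen afterwards, the means were 4.61% against 6.16%, 6.05% and 6.14% and the SD was 1.13 times the largest of the others, so part of the wider spread goes with chromosome 19. Cdkn2a lies on chromosome 4 and was counted at 115 CPM in these cells.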
